A study of Solanum lycopersicum and Solanum pennellii and Solanum pimpinellifolium with 52 samples.

How the data were processed

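RNA was sequenced from 52 libraries of tomato and its wild relatives. The first experiment held 28 libraries of seedlings grown on plates under standard light, 7 from each of 4 species: Solanum lycopersicum strain LA3475 (cultivated tomato), S. pimpinellifolium LA1589, S. habrochaites LA1777 and S. pennellii LA716 (3 wild relatives). The second experiment was a complete factorial of 24 libraries: S. pennellii and S. lycopersicum, 6 tissues (seedling, leaf, root, stem, inflorescence and vegetative meristem) and 2 light treatments, with 1 library per combination. Light in simulated shade had 0.48 parts of red per part of far-red, and light in simulated sun had 3.1; both averaged 95 µE. RNA of the factorial was extracted with Trizol and RNA of the seedling experiment with a Qiagen kit, and both were made into libraries with an Illumina mRNA kit, per the labels' protocols. The labels do not say whether libraries of one group came from separate plants or pools, so the p-values measure only the spread between libraries, which may be technical.

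The authors deposited one table of RPKM, that is, reads divided by the length of the gene model and by the total of the library. CASAVA 1.4 and BWA 0.5.7 (a short-read aligner) are named per the submitters' processing notes. The reference sequence, the counting rule and the treatment of reads that match several genes are not given in the sources used here. Reads of a wild species that differ from the reference may be counted less well, and near-identical gene copies may share reads, so a low value in one species can come from expression or from sequence. Each factorial library carries several run records in its label, and whether the runs were pooled before counting is not stated. All 52 value columns of the table were used.

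The RPKM values were whole multiples of the worth of 1 read. With a tolerance of 0.02 reads, 100% of the values above 0 came out whole, in all 25942 gene models with any value; the remaining 2356 gene models were at 0 in every library. The recovered totals ran from 1477052 to 5556065 reads per library, with a median of 2309108. The median implied gene length was 918 bases, and 77.0% of implied lengths were multiples of 3. On simulated tables the same procedure returned the drawn reads for 99.9% of values. At the median length and the median total, an RPKM of 1 stands for 2.12 reads, so low values carry large counting errors. A mean of 0 over a group was given a floor of 3 reads over the whole group, which covers counting error only.

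Tests were made on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior and robust estimation, and Benjamini-Hochberg adjustment over all genes tested in a comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The F tests used the adjusted p alone. Log2 differences on this scale understate the change of genes with low values. Seedling tests used 19536 genes with an RPKM of at least 1 in 7 or more of the 28 libraries, all 4 species in one fit with 24 residual degrees of freedom. A gene was apart in a species when it was called in one direction against each of the 3 other species. Factorial tests used 22512 genes with an RPKM of at least 1 in 2 or more of the 24 libraries. That model had a mean for each species and tissue and 1 light term per species, which leaves 10 residual degrees of freedom and takes the light response of a species as shared by its tissues. A gene was highest in a tissue when it was called higher there than in each of the 5 other tissues, averaged over species.

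The groups, the tests and the rule for naming genes were set before the data were examined. The rule named genes by the largest log2 difference among called genes whose groups of libraries did not overlap, with a mean RPKM of at least 5 in the higher group. For a light response of one species, all 6 pairs of the same tissue had to move one way. The table does not pair its IDs with gene names, and 0 of its IDs matched the RefSeq gene table of assembly SLM_r2.1. At most 2 IDs per direction are therefore named in a comparison. The gene lists and tissue markers planned by name were not used here. In their place, the genes highest in each tissue of the factorial served as gene sets for the seedling experiment, whose libraries are independent of the factorial. There, each set was cut to the genes tested in both experiments. These sets were chosen after the data were seen. They were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation; overlaps were tested with Fisher's exact test.

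Replicate libraries were compared as counts: over 84 pairs of seedling libraries of one species, the chi-square per gene ran from 1.93 to 18.4, so no library was a copy of another. The number ranges of the run records split the seedling libraries into 3 run blocks of 14, 12 and 2 libraries. What the blocks stand for is not stated. Seedling counts were recomputed within blocks 1 and 2. Block 3 holds 2 libraries of S. habrochaites alone and was not compared on its own. The median chi-square per gene was 3.70 for pairs within a block and 12.1 for pairs across blocks.

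The seedling contrast of S. pennellii and S. lycopersicum was tested on simulated reads in which 200 genes with a mean RPKM of at least 5 were changed. It recovered 28.4% of 2-fold, 91.0% of 4-fold and 98.5% of 8-fold changes, with 9 unchanged genes called among 19319 tested. The mean light contrast recovered 25.4%, 91.0% and 90.9%, with 1 unchanged gene called among 22187 tested. The light contrast within S. pennellii recovered 20.9%, 88.1% and 90.9%, with 5 unchanged genes called among 22180 tested. The spread was drawn independently for each gene and library, without shifts shared by a library or a run block. Recovery can therefore be overstated, and false calls understated, for the real libraries and for genes with lower values. Counting error was drawn on top of each gene's own spread, which already holds it, so recovery can also be understated. The net direction was not tested. Alternatives covered the pseudocount, the filter, median-ratio scaling, quantile normalization, a plain prior, an additive model, and leaving out each library or each tissue. A limma voom fit on the recovered reads, the run block as a covariate and fits within run blocks (with the genes of all 28 libraries, and with genes filtered within the block) were added after the data were seen.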

Results

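The study asked how gene expression differs between cultivated tomato and its wild relatives, and how it varies over tissues and in simulated shade. Expression was given as RPKM per gene model in 52 libraries. Of these, 28 were seedling libraries under standard light (7 each of S. lycopersicum, S. pimpinellifolium, S. habrochaites and S. pennellii), and 24 came from a factorial of 2 species, 6 tissues and 2 light treatments. Library totals lay between 1477052 and 5556065 reads. In the seedling experiment, the first principal component (30.2% of the variance of log2 values) set S. pennellii apart from the 3 other species. The second (20.3%) varied with species. Within each species, both components also varied with run block.

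**Figure D1:**
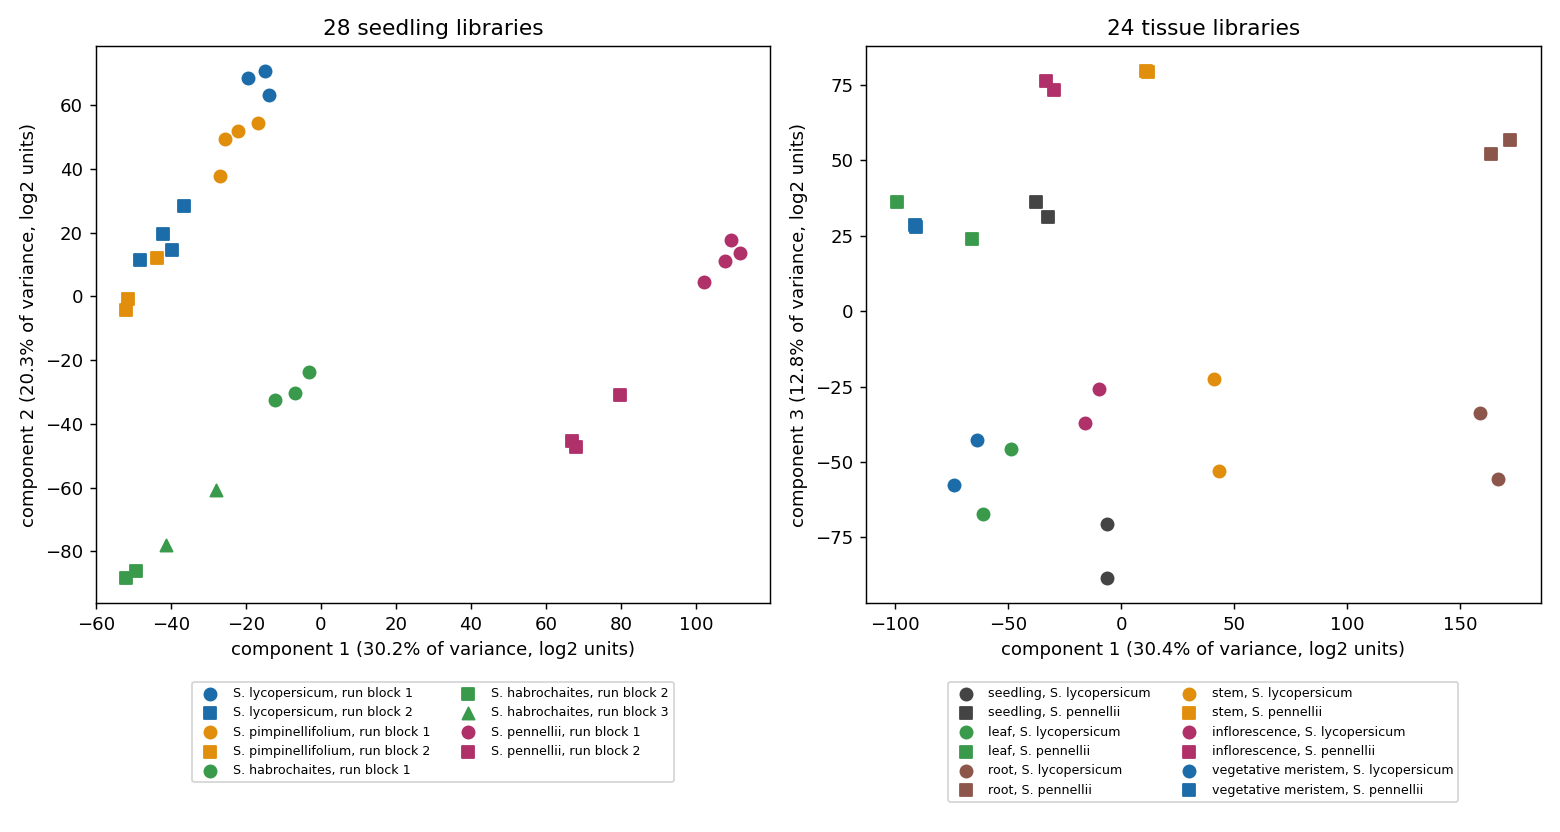
Principal component scores of each library, from log2(RPKM + 1) values, for the seedling experiment (left, colour by species and symbol by run block) and the tissue factorial (right, colour by tissue and symbol by species; component 3 is on the vertical axis). The S. pennellii seedlings lie to the right of all others, run blocks part within each species, and roots lie farthest right in the factorial.

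Seedlings of S. pimpinellifolium, a red-fruited close relative of cultivated tomato, differed from S. lycopersicum in 908 of 19536 genes, of which 355 were higher and 553 lower in the wild species. Gene Solyc12g088180.1.1 had 155 ± 61.6 RPKM in S. pimpinellifolium and 0.576 ± 0.993 in S. lycopersicum (SD, n = 7 each), a 269-fold difference (log2 difference 6.73 ± 0.31 SE, adjusted p = 4.6e-16). Gene Solyc08g068130.1.1 was 86.5-fold higher, at 387 ± 55.0 against 4.47 ± 2.65 RPKM (adjusted p = 9.9e-16). In the other direction, Solyc09g092040.2.1 had 142 ± 18.9 RPKM in S. lycopersicum and 2.26 ± 1.58 in S. pimpinellifolium (62.9-fold, adjusted p = 1.2e-12). Gene Solyc04g082910.1.1 had 282 reads over the 7 libraries of S. lycopersicum (65.6 ± 19.7 RPKM) and 1 read over those of S. pimpinellifolium (adjusted p = 9.3e-19). Within run block 1 the count was 948 genes (315 higher and 633 lower), and within run block 2 it was 862 (308 and 554). With the run block as a covariate it was 1039 (350 and 689).

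Seedlings of S. habrochaites, a green-fruited wild species, differed from S. lycopersicum in 2592 genes, 794 higher and 1798 lower. The 2 genes with the largest rise were Solyc12g088180.1.1, at 533 ± 197 RPKM (925-fold, adjusted p = 7.0e-19), and Solyc01g073970.2.1, at 333 ± 76.5 RPKM against 0.381 ± 0.654 in S. lycopersicum (adjusted p = 6.3e-19). Gene Solyc10g051380.1.1 had 151 ± 36.7 RPKM in S. lycopersicum and not a single read in the 7 S. habrochaites libraries, so it was at least 322-fold lower (floor of 3 reads over the group; adjusted p = 6.6e-22). Gene Solyc02g090840.2.1 fell from 163 ± 66.6 to 0.636 ± 1.03 RPKM (256-fold, adjusted p = 8.7e-15). The lean towards lower calls moved with the scaling of the libraries. As deposited, 30.6% of calls were higher in S. habrochaites. Median-ratio scaling gave 1017 higher and 1528 lower, and quantile normalization gave 1172 higher and 1332 lower (46.8% higher). Within run block 1 the count was 2508 genes (869 higher and 1639 lower). Within run block 2, with 2 S. habrochaites libraries, it was 2814 (605 and 2209). With the run block as a covariate it was 2802 (801 and 2001).

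Seedlings of S. pennellii, a green-fruited species of dry habitats, differed from S. lycopersicum in 3660 genes, 2302 higher and 1358 lower. Gene Solyc12g088180.1.1 was again high, at 362 ± 131 RPKM (628-fold, adjusted p = 2.7e-18). Gene Solyc11g021020.1.1 had 191 ± 59.2 RPKM in S. pennellii and no read in S. lycopersicum, at least 394-fold higher (adjusted p = 1.8e-23). Gene Solyc05g006740.2.1 had 135 ± 11.8 RPKM in S. lycopersicum and no read in the 7 S. pennellii libraries, at least 412-fold lower (adjusted p = 1.9e-29). Gene Solyc11g069880.1.1 had 975 reads in S. lycopersicum (94.2 ± 30.9 RPKM) and 1 read in S. pennellii (adjusted p = 5.6e-12). As deposited, 62.9% of calls were higher in S. pennellii, against 57.0% after median-ratio scaling and 52.3% (1929 higher and 1761 lower) after quantile normalization. Within run block 1 the count was 3821 genes (61.7% higher), and within run block 2 it was 3510 (57.8%). With the run block as a covariate it was 3712 (59.6%).

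**Figure D2:**
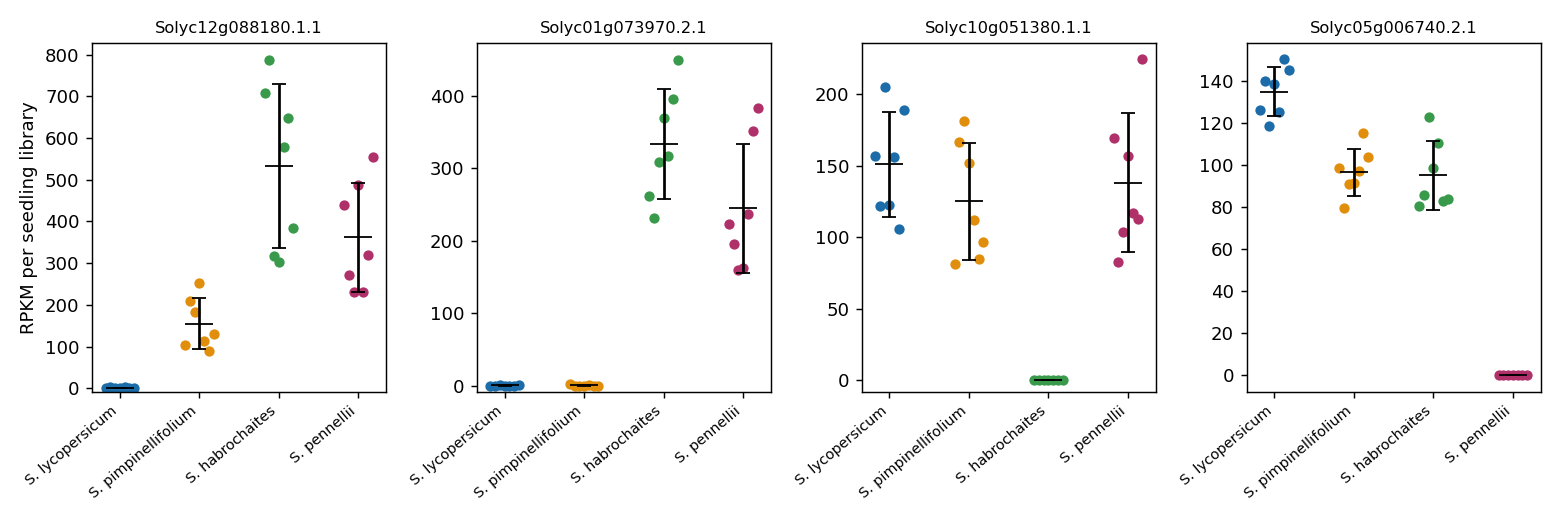
RPKM of 4 genes in each seedling library (points), with the mean and SD per species (bars, n = 7). Solyc12g088180.1.1 was near 0 in S. lycopersicum alone, Solyc01g073970.2.1 was high in S. habrochaites and S. pennellii, and Solyc10g051380.1.1 and Solyc05g006740.2.1 had no read in S. habrochaites and S. pennellii respectively.

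Among the wild species, S. pennellii and S. habrochaites differed in 4070 genes (3155 higher and 915 lower in S. pennellii). S. pennellii and S. pimpinellifolium differed in 3976 genes (2590 and 1386), and S. habrochaites and S. pimpinellifolium in 2122 (722 and 1400). Over all 4 species, 12861 genes (65.8% of those tested) differed by the F test, and 14531 with the run block as a covariate. The F test had no limit on the log2 difference. Without that limit the 3 pairs above gave 9345, 9114 and 5425 genes. The share of calls higher in S. pennellii than in S. habrochaites was 77.5% as deposited, 62.4% after median-ratio scaling (2374 and 1431) and 53.0% after quantile normalization (1956 and 1732). Against S. pimpinellifolium it was 65.1%, 59.8% and 52.3% (2091 and 1906 after quantile normalization). The share higher in S. habrochaites than in S. pimpinellifolium was 34.0%, 43.7% (905 and 1165) and 48.4% (1001 and 1067). Within run blocks 1 and 2 the 3 counts were 3768 and 4288, 4141 and 3914, and 2035 and 1911 genes. For S. habrochaites against S. pimpinellifolium the split was 869 higher and 1166 lower in block 1, and 456 and 1455 in block 2. The share higher in S. pennellii than in S. pimpinellifolium was 67.6% in block 1 and 58.8% in block 2. Against S. habrochaites it was 74.1% and 77.2%. Which of the first 2 comparisons had more genes turned with the setting: after median-ratio scaling S. pennellii differed from S. pimpinellifolium in 3926 genes and from S. habrochaites in 3805.

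Genes that set one species apart from each of the 3 other species were most frequent in S. pennellii: 1644 genes, 1293 higher and 351 lower. S. habrochaites was apart in 567 genes (136 higher and 431 lower), S. lycopersicum in 287 (204 and 83) and S. pimpinellifolium in 166 (83 and 83). In S. pennellii, Solyc06g075990.2.1 had 166 ± 105 RPKM (n = 7) against 1.05 ± 2.62 in the 21 libraries of the other species, and Solyc05g006740.2.1 had no read against 109 ± 22.7 (at least 332-fold lower). In S. habrochaites, Solyc02g092860.2.1 was 97.3-fold higher than in the other species (113 ± 30.8 against 1.16 ± 1.76 RPKM). In S. lycopersicum, Solyc09g092040.2.1 was 92.2-fold higher and Solyc12g088180.1.1 was 607-fold lower than in the wild species. In S. pimpinellifolium, Solyc03g005800.2.1 had 149 ± 10.9 RPKM against 7.42 ± 2.44 in the other species. For S. pennellii, median-ratio scaling gave 1070 higher and 453 lower and quantile normalization 964 and 608. For S. habrochaites they gave 189 higher and 334 lower, and 243 and 283. With a pseudocount of 0.1 there were more lower genes: 691 in S. habrochaites (140 higher), 151 in S. lycopersicum (174 higher) and 137 in S. pimpinellifolium (75 higher). Within run blocks 1 and 2 the counts were 1618 and 1426 for S. pennellii, 537 and 674 for S. habrochaites, 300 and 244 for S. lycopersicum, and 153 and 125 for S. pimpinellifolium.

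The set of genes highest in the stem of the factorial had a lower median than all genes in the seedlings of each wild species against S. lycopersicum. Of the 408 stem genes, 364 were also tested in seedlings. Their median log2 difference was −0.28 in S. pimpinellifolium, −0.52 in S. habrochaites and −0.34 in S. pennellii. The medians of all genes were −0.00, −0.14 and 0.10. The camera test called the set lower in each (adjusted p = 5.5e-08, 9.3e-07 and 1.7e-07), but none of the calls held with an estimated correlation (adjusted p = 0.077, 0.13 and 0.095). Among its members, 4 were called higher and 24 lower in S. pimpinellifolium, 12 and 69 in S. habrochaites, and 26 and 76 in S. pennellii. The 3 comparisons share the same 7 S. lycopersicum libraries and are not independent. Of the 59 genes highest in factorial seedlings, 28 were called higher and 11 lower in S. pennellii, with a median of 0.81 (adjusted p = 0.0038; adjusted p = 0.18 with an estimated correlation). Against S. habrochaites the median of this set was 1.16, with 32 members higher and 3 lower. The call held with an estimated correlation (camera adjusted p = 1.0e-05 and 0.046). Against S. pimpinellifolium the median was 1.13, with 32 members higher and 4 lower, and the call did not hold (adjusted p = 2.6e-05, and 0.060 with an estimated correlation). These p-values were adjusted over the tissue sets of each comparison, not over all 36 seedling set tests. The set was cut from 60 genes, a count that 4 of 100 splits of the factorial libraries reached, so chance is not excluded for that count. In S. habrochaites against S. lycopersicum the seedling set had a median of −0.69, with 3 members higher and 22 lower (adjusted p = 0.0075; adjusted p = 0.23 with an estimated correlation). The leaf set (median 0.42, 58 members higher and 18 lower) and the root set (median 0.35, 247 and 95) were called higher in S. pennellii than in S. lycopersicum by camera, each with adjusted p = 0.026; with an estimated correlation the adjusted p was 0.74 and 0.72. The inflorescence set was called higher in S. habrochaites than in S. lycopersicum (median 0.09, adjusted p = 0.0080; adjusted p = 0.81 with an estimated correlation), although 23 members were called higher and 39 lower. The vegetative meristem set was not called in S. pimpinellifolium, S. habrochaites or S. pennellii against S. lycopersicum (adjusted p = 0.077, 0.82 and 0.76).

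**Figure D3:**
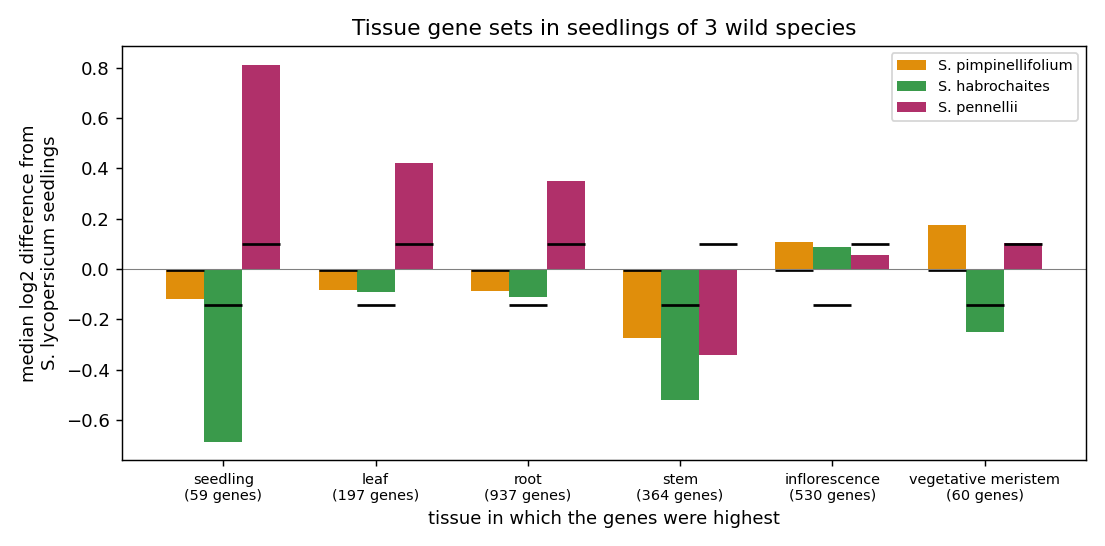
Median log2 difference from S. lycopersicum seedlings (vertical axis) of the genes highest in each tissue of the factorial (horizontal axis, with the number of genes), for 3 wild species (bars); black lines give the median of all genes tested. The stem set lies below the line in all 3 species, and the seedling set lies above it in S. pennellii and below it in S. habrochaites.

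The species difference was also present in the factorial. Averaged over 6 tissues, 2384 of 22512 genes differed between S. pennellii and S. lycopersicum, 895 higher and 1489 lower in S. pennellii. Gene Solyc12g088180.1.1 had 613 ± 305 RPKM in the 12 S. pennellii libraries and 0.873 ± 1.41 in the 12 of S. lycopersicum (702-fold, adjusted p = 3.1e-12), and Solyc01g073970.2.1 had 268 ± 153 against 1.70 ± 1.99 (157-fold, adjusted p = 9.0e-12). Gene Solyc03g034200.2.1 was 724-fold lower in S. pennellii, at 0.0762 ± 0.122 against 55.2 ± 18.6 RPKM (adjusted p = 1.1e-13). Gene Solyc01g104710.2.1 had 450 reads in S. lycopersicum and 2 in S. pennellii (adjusted p = 1.6e-10). The share of higher calls was 37.5% as deposited, 46.3% (1070 and 1243) after median-ratio scaling and 48.6% (1124 and 1189) after quantile normalization. The number of differing genes per tissue was 2726 in stem, 2488 in root, 2413 in seedling, 2143 in leaf, 1948 in inflorescence and 1279 in vegetative meristem. With a pseudocount of 0.1 the mean over tissues gave 3947 genes, and limma voom gave 4013.

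**Figure D4:**
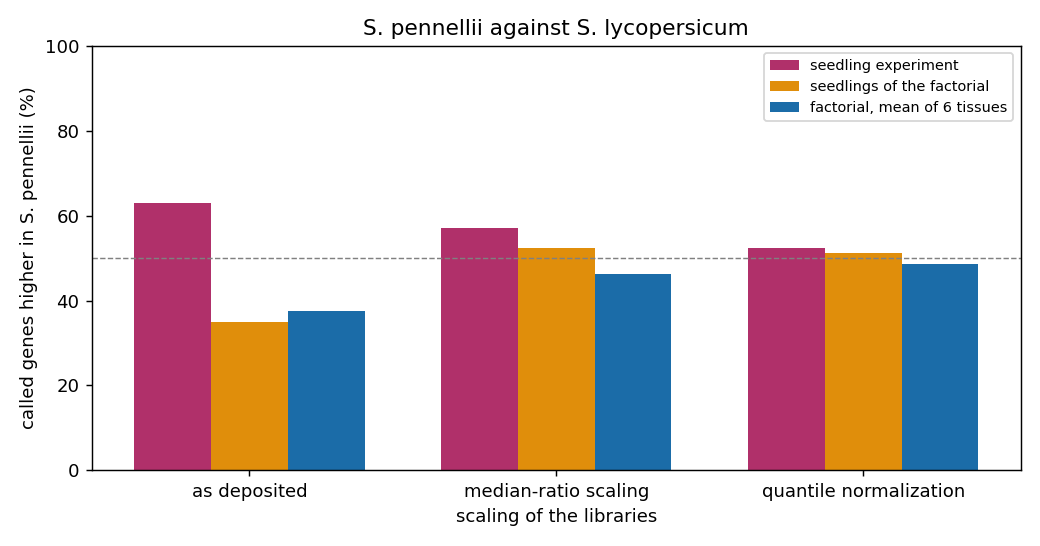
Percent of called genes that were higher in S. pennellii than in S. lycopersicum (vertical axis, dashed line at 50%), in the seedling experiment, in the seedlings of the factorial and in the mean of 6 tissues (bars), for 3 scalings of the libraries. The bars of the seedling experiment and the factorial seedlings stand at 62.9% and 35.0% as deposited and at 52.3% and 51.1% after quantile normalization.

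The difference between S. pennellii and S. lycopersicum seedlings was compared across the 2 experiments over 19438 genes; the factorial has 4 seedling libraries, 1 per species and light. Pearson's r was 0.567 and Spearman's rho 0.427, across genes, which are not independent replicates. Of 3635 genes called in the seedling experiment, 79.4% had the same sign in the factorial seedlings: 73.7% of those higher in S. pennellii and 89.0% of those lower. These 2 shares were 80.8% and 83.9% after median-ratio scaling and 81.0% and 81.9% after quantile normalization. The sets of genes apart in seedlings, cut to the genes tested in both experiments, were also tested in each tissue of the factorial. The set of 83 genes lower in S. lycopersicum than in all wild species was called higher in S. pennellii in each of the 6 tissues, where 32 (inflorescence) to 48 (seedling) members passed as higher and at most 2 as lower, with medians from 1.21 in inflorescence to 1.85 in seedling, and adjusted p = 0.00016 and 8.8e-05 there with an estimated correlation. The set of 201 genes higher in S. lycopersicum was called lower in S. pennellii in each tissue, where 49 (root) to 103 (seedling) members passed as lower and at most 6 as higher, with medians from −0.53 in root (adjusted p = 0.046 with an estimated correlation) to −1.66 in seedling (adjusted p = 0.0012 with it). The set of 350 genes lower in S. pennellii was called lower in each tissue, where 89 (root) to 163 (seedling) members passed as lower and at most 12 (stem) as higher, with medians from −0.67 in root to −1.40 in seedling, and adjusted p = 0.014 and 0.00055 there with an estimated correlation. The 1284 genes higher in S. pennellii had a median of 0.63 in seedling (293 members higher and 22 lower) and 0.63 in vegetative meristem (221 and 7; adjusted p = 0.013 and 0.015 with an estimated correlation). In leaf, root, stem and inflorescence their call did not hold with an estimated correlation (adjusted p = 0.073, 0.12, 0.27 and 0.18).

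Roots had the most distinct expression of the 6 tissues: 1797 genes were higher in root than in every other tissue, averaged over both species. Gene Solyc03g091000.1.1 had 604 ± 279 RPKM in the 4 root libraries and 1.47 ± 3.48 in the 20 others (412-fold), and Solyc03g093060.1.1 had 345 ± 192 against 0.846 ± 2.05. Inflorescence had 633 such genes, among them Solyc07g006380.2.1 (1915 ± 2367 against 3.74 ± 4.98 RPKM) and Solyc05g015750.2.1 (51.7 ± 30.1 against 0.144 ± 0.285). Stem had 408, with Solyc10g049580.1.1 at 2807 ± 1317 against 181 ± 210 RPKM. Leaf had 219, with Solyc01g010480.2.1 at 526 ± 234 against 23.1 ± 28.5 RPKM. Vegetative meristem had 63, with Solyc04g054740.2.1 at 913 ± 206 against 158 ± 145 RPKM, and seedling had 60, with Solyc08g021820.2.1 at 82.5 ± 59.5 against 2.66 ± 3.59 RPKM. In the opposite direction, 790 genes were lower in leaf than in every other tissue and 735 in root. The leaf count rose to 475 after median-ratio scaling and 407 after quantile normalization, and the inflorescence count fell to 261 and 382. The species difference varied between tissues in 1905 genes (F test of the species by tissue interaction, with no limit on the log2 difference), and in 1139 with a pseudocount of 0.1. This count was 984 and 1224 without the S. pennellii sun and shade root library, 1220 and 1214 without its shade and sun meristem and 1223 without its sun stem. The meristem count of 63 was 17 and 35 without the S. pennellii shade and sun meristem, 28 and 36 without its shade and sun seedling, and 37 without its shade leaf. Without S. lycopersicum libraries it was 34 and 35 (shade and sun meristem), 34 (sun leaf) and 21 (sun seedling), and with a pseudocount of 0.1 it was 38.

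Simulated shade, a low red to far-red ratio such as plants sense under the leaves of neighbours, was compared with simulated sun in the same libraries. For the mean of both species, 0 of 22512 genes passed the limma test, and limma voom called 2. At an unadjusted p under 0.05 in limma there were 1050 genes (4.66%), where chance gives about 5%. In S. lycopersicum 0 genes passed (1239 or 5.50% unadjusted, voom 0), and the species by light interaction called 0 (1591 or 7.07% unadjusted, voom 0). In S. pennellii 2 genes passed (1398 or 6.21% unadjusted, voom 40), both higher in shade. Gene Solyc11g063500.1.1 had 311 ± 150 RPKM in shade and 47.5 ± 54.8 in sun (SD, n = 6), with a log2 difference of 3.31 ± 0.47 (SE). Gene Solyc12g010550.1.1 had 67.3 ± 94.3 in shade and 21.2 in sun (range 0 to 81.3), with a log2 difference of 1.48 ± 0.20. Both had an adjusted p of 0.0495 in limma and were higher in shade in 6 of 6 S. pennellii pairs and 4 of 6 S. lycopersicum pairs of one tissue. After median-ratio scaling both missed the threshold (adjusted p = 0.073), and the S. pennellii count was also 0 with no filter, with a plain prior and with the additive model. Leaving out a single library moved it between 0 and 11: it was 0 or 1 without any one S. pennellii library (without either stem library the 1 gene was lower in shade, so both named genes were lost) and 11 without either S. lycopersicum meristem. Each species and tissue has its own mean in the fit, so leaving out either library of a pair takes the whole pair out of the light estimate. On simulated reads the mean light contrast recovered 91.0% of 4-fold and 25.4% of 2-fold changes shared by both species and all tissues. The changed genes had a mean RPKM of at least 5, and shifts shared by the genes of a library were not simulated. A response limited to one tissue has 1 library per light and species here.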

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

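The tests of meristem tissue, of library scaling, of read mapping and of the number of libraries per light treatment were chosen after the results they bear on had been seen, as was the comparison of run blocks.

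Seedling libraries differed between run blocks within every species. Block 2 (12 libraries) had 1546 called genes against block 1 (14 libraries), 111 higher and 1435 lower, with species in the fit, and the highest count in 99 other splits of the libraries within species was 1. Thinning all libraries to 1477052 reads left 1589 called genes, and median-ratio scaling left 1132 (287 higher and 845 lower), so depth and a few abundant genes are both argued against as the whole cause. The 60 genes highest in vegetative meristem had a median difference of −0.80 (block 2 minus block 1, against −0.27 for all genes), with −0.81 in S. lycopersicum, −0.65 in S. pimpinellifolium, −1.05 in S. habrochaites and −0.67 in S. pennellii. Less meristem tissue in the harvest is a candidate explanation (p = 0.0265 with an estimated correlation), though over the 6 tissue sets the adjusted p is 0.159; the day, the growth batch and the library batch stay open, since the labels do not say what the blocks are.

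Calls between S. pennellii and S. lycopersicum leaned opposite ways in the 2 sets of seedlings: 62.9% were higher in S. pennellii in the seedling experiment and 35.0% in the factorial seedlings, a gap of 27.9 points. After median-ratio scaling the gap was 4.52 points, and after quantile normalization 1.14; both centre the libraries, which pulls the calls towards an even split whatever made them lean, so scaling as the cause stays open. Thinning to one depth left it at 28.4 points, which argues against depth. Poorer mapping of S. pennellii reads, if it acted alike in both experiments, would not by itself make them lean opposite ways. Whether it adds to the lower calls in the factorial seedlings stays open. The library totals hold almost only reads in the listed genes (99.996% to 100%), so a loss spread over all genes cancels. Reads lost by some genes raise the values of the others. The share of higher calls was 62.9% in the seedling experiment (57.0% after median-ratio scaling) and 35.0% in the factorial seedlings. It therefore cannot decide how much poorer mapping adds to the lean of either experiment. Light, growth conditions and RNA extraction differed between the experiments and were not tested.

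Almost no gene passed for shade against sun. Too few libraries for any call is argued against only for differences as large as those between the species. The species contrast of the same 24 libraries has the same standard errors (ratio 1) and called 2384 genes. That count does not show that the libraries suffice for smaller light responses. With the limit on the log2 difference, responses of 2-fold would mostly be missed (25.4% recovered on simulated reads). Without that limit, limma still gave 0 genes for the mean of both species and 2 in S. pennellii. It gave 0 in S. lycopersicum and 0 for the interaction. Responses that differ between tissues but are shared by both species would make shade differences of the same tissue correlate across genes more than those of different tissues. The mean correlation was −0.0851 for the 6 matched tissues and 0.00124 for other pairings (exact one-sided p = 0.986 over 720 pairings). It was 0.1003 in vegetative meristem and negative in the 5 other tissues, but its sign rests on the light labels of S. lycopersicum, where swapping those of 4 tissues gave 518 genes against 0 with the real ones, so such responses stay open, as do small ones.

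Other splits of the same libraries were counted for each result. For all 6 pairs of species, 1 of 100 splits (the real one) gave as many genes. The real and highest other counts were 908 and 355 for S. pimpinellifolium, 2592 and 1153 for S. habrochaites and 3660 and 2269 for S. pennellii against S. lycopersicum. They were 2122 and 1247 for S. habrochaites against S. pimpinellifolium, and 3976 and 2492 and then 4070 and 2558 for S. pennellii against S. pimpinellifolium and S. habrochaites. It was also 1 of 100 for the difference among any species (12861, highest other 21) and for the genes apart in S. lycopersicum (287), S. pimpinellifolium (166), S. habrochaites (567) and S. pennellii (1644), where the highest other was 0. In the factorial it was 1 of 100 for the species effect (2384, highest other 920) and for leaf (219 and 31), root (1797 and 359), stem (408 and 52), inflorescence (633 and 82) and vegetative meristem (63 and 46). The 60 seedling genes were reached by 4 of 100 splits, with 93 as the highest other. For each result above, under 5% of the splits reached the real count, with no adjustment for the number of results. For the 60 seedling genes, which 4 of 100 splits reached, chance is therefore not excluded. For the S. pennellii light response, 1 of 32 swaps of light labels within tissues gave 2 genes, with 0 as the highest other. Against a count of 0 every split gives as many genes, so the 100 of 100 splits for the mean light response (highest other 108) and for the species by light interaction (highest other 4), and the 32 of 32 for S. lycopersicum, say nothing about chance. In S. lycopersicum, swapping the labels of leaf, seedling, stem and vegetative meristem gave 518 genes, which points to a structure of the S. lycopersicum libraries that the light labels do not follow.

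One library lay far from the others of its group in 12 of 53 groups of named values. A rate of 1 in 20 would give 2.65, but it holds only for replicate libraries with normally spread values. Some flagged groups had reads in a single library, and others mixed tissues, or species and light treatments. The count of 12 therefore cannot be set against 2.65, and no conclusion on chance is drawn. Over the seedling groups of each named gene in all 4 species the count was 18 of 74. In 5 groups with 5 or fewer reads in total, S. pimpinellifolium replicate 12 had 1.10 RPKM of Solyc04g082910.1.1, S. pimpinellifolium replicate 14 had 0.385 of Solyc03g081260.2.1, S. pennellii replicate 24 had 0.579 of Solyc11g069880.1.1, S. pennellii replicate 28 had 3.44 of Solyc08g067540.1.1 and S. habrochaites replicate 15 had 2.80 of Solyc02g090840.2.1. S. habrochaites replicate 17 had 120 RPKM of Solyc03g114530.2.1, against 80.1 in the next library. In S. pennellii both light genes were highest in root in sun, and Solyc12g010550.1.1 also in shade. Solyc11g063500.1.1 had 151 RPKM in the S. pennellii sun root against 59.7 in the next tissue. Solyc12g010550.1.1 had 256 in the shade root against 48.9 and 81.3 in the sun root against 14.6. The S. pennellii shade leaf had 877 RPKM of Solyc01g010480.2.1, against 421 in the next leaf library. The S. lycopersicum shade meristem had 19.96 RPKM of Solyc02g079490.2.1 against 10.5, and 1222 of Solyc04g054740.2.1 against 822. The difference between S. pennellii and S. lycopersicum itself varied between tissues in 1905 genes (species by tissue interaction; 984 without the S. pennellii sun root).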

How the results depend on the processing

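The run block settings, the voom fit and all tissue set tests were chosen after the data were seen. All 11 seedling counts stayed within 1.5 times of their values under every setting run, with the exception of 2 counts within run block 2 once genes were filtered on the libraries of that block, which leaves fewer genes to test. There S. lycopersicum was apart in 183 genes and S. pimpinellifolium in 96. The split of seedling calls into higher and lower moved with scaling and run block, as given above. For genes apart it also moved with a pseudocount of 0.1. With voom S. lycopersicum was apart in 244 higher and 141 lower genes. With genes filtered within run block 2, higher genes were fewer by over 1.5 times for S. habrochaites against S. lycopersicum (444) and against S. pimpinellifolium (324), and for genes apart in S. lycopersicum (116), S. pimpinellifolium (28), S. habrochaites (45) and S. pennellii (782). Filtered within block 1 this held for S. pimpinellifolium apart (39). The filter still asked for an RPKM of at least 1 in 7 libraries, and each of these blocks holds at most 4 of a species. Genes at that level in a single species could not pass, so these falls can come from the filter alone. The factorial was less stable; the cause was not tested except where given. With a pseudocount of 0.1, S. pennellii had 4 light genes, the species effect had 3947 genes, vegetative meristem 38, the species by tissue interaction 1139, and the correlation between experiments was 0.591. With no filter, S. pennellii had 0 light genes and the correlation was 0.548. Median-ratio scaling gave 0 light genes in S. pennellii, 475 leaf and 261 inflorescence genes; quantile normalization gave 7, 407 and 382. A plain prior gave 0 light genes in S. pennellii, and the additive model gave 0 and 33 meristem genes. With voom the mean light response had 2 genes, S. pennellii 40 and the species effect 4013. Leaving out 1 library leaves 1 in its species and tissue, which is assumed to vary like the rest. The S. pennellii light count then ran from 0 to 11: each S. pennellii library (the 1 gene without either stem library was lower in shade) and both S. lycopersicum leaf libraries gave 0 or 1, as did the S. lycopersicum seedling libraries and shade root, both its meristem libraries gave 11, and its inflorescence and stem libraries and sun root moved it by less than 1.5 times. The mean light count ran from 0 to 2 and the S. lycopersicum count from 0 to 4, the higher values without either S. lycopersicum root library; the species by light interaction ran from 0 to 1, with 1 without either of those or either S. pennellii inflorescence. The meristem count of 63 ran from 17 to 80 and the species by tissue interaction of 1905 from 984 to 2186, with the libraries that moved them named above. Leaving out a tissue, the mean light count ran from 0 to 4 (4 without root), S. pennellii from 0 to 3 (0 without seedling, inflorescence or meristem, 1 without leaf), S. lycopersicum from 0 to 2 (2 without root, 1 without seedling) and the interaction from 0 to 1 (1 without root). The correlation between the seedlings of the 2 experiments ran from 0.509 to 0.574 with 1 library left out. Of the alternatives run for each named gene (pseudocount, median-ratio scaling and quantile normalization), 136 kept direction and side of the threshold and 2 lost the call (the 2 light genes after median-ratio scaling). Of 36 tissue set tests in seedlings 15 were called. With an estimated correlation 14 of the 15 lost the call, all but the seedling set in S. pennellii against S. habrochaites. The p-values were adjusted within each comparison, not over the 36 tests. With median-ratio scaling, quantile normalization, a pseudocount of 0.1 or the run block as a covariate, 14 kept it, and the leaf set in S. habrochaites against S. pimpinellifolium lost it each time. Sets that gained a call numbered 2 with either scaling and 1 with the run block. Scaling moved the median of all genes by over 0.1: S. pennellii minus S. habrochaites went from 0.25 to 0.06 (median-ratio) and −0.05 (quantile), and S. habrochaites minus S. lycopersicum from −0.14 to −0.03 and 0.02. The planned tests of named gene lists were not run, since no ID matched the RefSeq gene table that was tried. Thinning all libraries to 1477052 reads left the calls between S. pennellii and S. lycopersicum near their counts in the seedling experiment (2318 higher and 1331 lower) and lowered those in the factorial seedlings from 845 higher and 1568 lower to 613 and 1131. Of simulated 2-fold changes 28.4% were recovered in seedlings; a 2-fold change lies at or under the threshold of 1 on the log2(RPKM + 1) scale at any depth.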

Other observations

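The tests in this part were chosen after the data were seen. Overlaps of gene lists were counted among the 19438 genes tested in both experiments, so some lists are shorter than above. Genes that were higher in S. pennellii seedlings than in each other species overlapped with genes highest in particular tissues of the factorial. Of 1284 such genes, 154 were root genes (61.9 expected from independent lists), 33 leaf genes (2.54 times the expected number) and 24 seedling genes (3.90 expected), with adjusted p = 5.2e-25, 1.1e-05 and 2.1e-12 by Fisher's exact test over 48 overlaps. Only 14 were stem genes, against 24.04 expected (adjusted p = 0.11). Among 114 genes higher in S. habrochaites, 18 were root genes (5.50 expected, adjusted p = 8.1e-05). Among 201 genes higher in S. lycopersicum, 22 were root genes (9.69 expected, adjusted p = 0.0027), 15 inflorescence genes (5.48 expected, adjusted p = 0.0029) and 7 seedling genes (0.610 expected, adjusted p = 3.0e-05). Fisher's test takes genes as independent, and genes of one tissue are not.

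Some genes well expressed in other species had no read in one. Among genes with at least 5 RPKM on average in each of the 3 other species, 15 of 12096 had no read in the 7 S. pennellii libraries (0.124%, exact 95% interval 0.0694 to 0.204%), and 7 of the 15 also had none in the 12 S. pennellii libraries of the factorial. In S. habrochaites it was 14 of 12391 (0.113%, 0.0618 to 0.19%), in S. lycopersicum 4 of 11973 (0.0334%, 0.0091 to 0.0855%) and in S. pimpinellifolium 0 of 11970 (up to 0.0308%). Of the 15 S. pennellii genes, 0 lacked reads in the 12 S. lycopersicum libraries of the factorial. Of the 4 S. lycopersicum genes, 1 also had no read in those 12 libraries, and 0 lacked reads in the 12 of S. pennellii. The intervals cover counting error only.

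Called genes were often neighbours in the order of the gene IDs, which by their naming convention follows the chromosomes. Of 353 genes higher in S. pimpinellifolium than in S. lycopersicum, 33 adjacent pairs were both called, against a mean of 6.37 in 1000 shuffles of gene order (5.18 times as many). For lower genes it was 50 pairs against 15.6. The ratio was smaller with more calls: 64 against 31.9 (higher) and 284 against 164 (lower) in S. habrochaites, and 393 against 269 and 184 against 92.4 in S. pennellii. Each of these counts had a permutation p of 0.001, the smallest that 1000 shuffles can give. Neighbouring copies of one gene, which can share reads, were not separated from other neighbours.

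In the light contrasts, camera with a preset correlation called some tissue sets, none of which held with an estimated correlation; the sets were defined in the same libraries. In S. pennellii the 408 stem genes had a median shade minus sun difference of 0.15 and the 63 meristem genes −0.35, against −0.05 for all genes (adjusted p = 5.7e-09 and 1.6e-06; adjusted p = 0.10 and 0.38 with an estimated correlation). In S. lycopersicum the meristem genes had a median of 0.28 against 0.07 for all genes (adjusted p = 0.00023; adjusted p = 0.58 with an estimated correlation). The difference between the species was −0.70 for the meristem set (adjusted p = 8.8e-09; adjusted p = 0.44 with an estimated correlation).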
